A study of Mus musculus with 9 samples.

How the data were processed

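Gene expression was measured on bead arrays in 9 samples of mouse nuclear-transfer embryonic stem cells (ntESCs), which are pluripotent lines derived from embryos made by placing a somatic nucleus into an egg without its own nucleus. The 9 samples fell into 3 genotypes of Terc, the gene for the RNA component of telomerase, with 3 arrays each: Terc+/+, Terc+/- and Terc-/-. Per the labels, the background was C57BL/6, and the 3 samples of a genotype were biological repeats. Whether they came from separate lines or from separate cultures of 1 line was not stated, so the spread between arrays may be partly technical. Per the labels' protocols, the cells were grown in serum-free medium with LIF on embryonic fibroblasts (MEFs) stopped by mitomycin-C, and were trypsinized and freed of the fibroblasts before RNA was extracted, treated with DNase and amplified into biotin-labelled cRNA. The batches in which the lines were derived or cultured were not given in the sources used here.

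The values analysed were log2 values that the authors deposited in the value table of the series, 1 per probe and array. The unit and its processing were not stated by the labels, and were read from the values. All 9 columns ran from about 5.11 to 14.8 with medians of 5.94 and almost equal upper quartiles (7.73), as quantile-normalized values do. The highest value is a signal of 28834.7 if the base is 2, and of 2718300 if it is the natural base, which a 16-bit scanner with its limit of 65536 cannot give, so log2 was taken as the scale. Values were not centred per gene. The software and any background correction by the authors were not given in the sources used here.

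A table of raw signals with detection p-values was also deposited by the authors, but its 18 columns (signal and detection p of 9 arrays) are named by chip and position only and match no sample label. They were not assigned to samples by order or by values and were not used here. The column names show 8 arrays on 1 chip and 1 array on another, without telling which sample that was. The planned main setting had been normexp background correction, quantile normalization and a detection filter on raw signals. It was replaced by the deposited log2 values without a filter, which had been listed before the data were examined as another choice of values. Settings that need raw signals or detection p-values were not run.

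Of 25697 probes, 23141 were paired with 1 gene symbol in the platform annotation, 0 with several and 2556 with none. All 23141 were matched by Entrez identifier to the RefSeq gene table of mouse assembly GRCm38.p6, which changed 0 symbols. No genome build is named in the files, so coordinates are not given. Of the 16110 named genes, 4507 had more than 1 probe. Each gene was represented by its probe with the highest mean over all 9 arrays, and unnamed probes were tested as probes, which gave 18666 features.

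The 3 genotypes were fitted in 1 linear model with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes, 6 residual degrees of freedom, prior degrees of freedom 2.03). The comparisons were Terc-/- against Terc+/+, Terc+/- against Terc+/+ and Terc-/- against Terc+/-. A feature was called at a Benjamini-Hochberg adjusted p under 0.05 within a comparison, two-sided. All adjusted p-values of genes come from limma. The number of arrays limits the precision: the median standard error of a log2 fold change was 0.11.

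A set of 30 gene lists was fixed before the data were examined and tested with limma's camera at a preset correlation between genes of 0.01, with adjustment over the 30 lists of a comparison. The lists covered telomerase and telomere proteins, two-cell-like genes, naive and core pluripotency, primed epiblast, neuroectoderm, mesoderm and primitive streak, endoderm, trophoblast, epidermis and keratinocytes, embryonic fibroblast feeder cells, macrophages and blood, and endothelium. They further covered p53 targets, DNA damage signalling and repair, mitochondrial biogenesis regulators, oxidative phosphorylation, glycolysis, hypoxia-induced genes, the amino acid and ER stress response, the heat shock response, cholesterol synthesis, immediate early genes, and the cell cycle. The last were DNA methylation and demethylation, methylation-silenced germline genes, imprinted genes, Y-linked genes with Xist, the interferon response, TGF-beta and BMP targets, and Wnt targets. Beside camera, the same lists were tested with a correlation estimated from the data and with fry, a rotation test of whether the genes of a list move one way on balance. An array's score for a list was the mean, over its members, of the deviation from each member's mean over the 9 arrays.

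Named genes followed a rule set before the data were examined. Terc came first. In the comparisons against Terc+/+, the 10 largest rises and the 10 largest falls were named among called genes whose 3 arrays all lay on 1 side of the other genotype's arrays, and in Terc-/- against Terc+/- the first 5 of each, leaving out predicted and unnamed genes. In each list, the 3 called members of smallest p were named. With fewer than 5 calls, the 5 genes of smallest p in each direction were given as values not past the threshold. Y-linked genes, Xist, Pou5f1, Nanog, Sox2 and Zscan4 genes were always to be given. Members of lists named as examples outside this rule were chosen after their values were seen.

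Alternatives planned before the data were examined covered normalization, arrays entering the fit, the replicate number as a block, the variance model, array weights, several probes of a gene, a minimum fold and leaving out each array. Added after seeing the data were cyclic loess and a background subtraction applied to the deposited values (the 5th percentile of all signals, offset 16), filters on a gene's mean value, and a fit with the feeder score as a covariate (5 residual degrees of freedom). A correlation across arrays was tested by an exact permutation test over all 362880 orders of the 9 arrays. Chance values of shared control arrays were simulated 1000 times by giving whole residual arrays a random order and sign. The simulation was changed 2 times for technical reasons, the second time after its values had been seen, which left the upper bounds nearly as they were. After the result was seen, the rule for rejecting shared controls as the cause was also made stricter: the covariance now has to exceed the sampling error of the simulated upper bound, and the simulated bound of the model without the feeder score as well. For a genotype difference alone in the two-cell-like genes, and for a feeder difference between genotypes, the first tests (overlap of Terc+/- arrays with the others, whose bound had been raised after its value was seen, and counts of calls) were replaced after their values were seen by tests on correlation around the genotype means and on the share of the log2 difference kept with the feeder score.

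The scripts were tested on simulated data with the real genes' spread for Terc-/- against Terc+/+. The noise was independent between genes and arrays, so the rates below leave out variation that many genes of an array share. Among 18666 genes, with 50 changed at each size, 56% of 1.5-fold, 62% of 2-fold, 92% of 4-fold and 98% of 8-fold changes were called, with 11 false calls. A shift of 0.5 in the glycolysis list was called, with 0 of the other lists. In a further simulation every gene had the same spread, and a feeder axis was built from the very score that was then fitted. There, 100 of 100 genes changed by 2-fold were called with the score in the fit and 3 without it. This tests the script and gives no rate for the real arrays.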

Results

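The data compared genome-wide expression between ntESCs with both copies, 1 copy or no copy of Terc, with 3 arrays per genotype. Terc encodes the RNA template that telomerase copies onto chromosome ends. The comparisons address how the transcriptome differed with the Terc dose. No probe was paired with Terc or with Nanog in the annotation used (0 probes each), so the targeted gene was not analysed here and the genotypes rest on the labels. The deposited log2 values correlated between 0.950 and 0.995 for every pair of arrays across probes, which are not independent replicates. The 9 pairs within a genotype had a median correlation of 0.985 and the 27 pairs between genotypes 0.982.

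Fibroblast genes varied most between arrays of 1 genotype. The feeder layer expresses collagens, lysyl oxidase (Lox), the proteoglycans Bgn and Dcn, vimentin (Vim) and Thy1, all of which differentiating mesenchymal cells make too. Over the 42 measured feeder markers, the array score spanned a 4.89-fold range, from -1.16 in Terc+/+ replicate 3 to 1.13 in Terc-/- replicate 3. Of these markers, 33 were lowest in Terc+/+ replicate 3 and 26 were highest in Terc-/- replicate 3. Lox ranged 29.2-fold and Col1a1 12.1-fold over the arrays. Mean scores were -0.13 ± 1.01 in Terc+/+, -0.22 ± 0.88 in Terc+/- and 0.35 ± 0.69 in Terc-/- (SD, n = 3), so the spread within a genotype exceeded the differences between genotypes. The first principal component held 46.3% of the variance. Computed without the feeder markers, it followed the feeder score with Pearson's r = 0.937 (exact permutation p = 5.51e-06, two-sided, adjusted 1.65e-05 over 3 relations, n = 9) and Spearman's rho = 0.983 (exact permutation p = 4.96e-05, adjusted 0.000149). These p-values are not particular to the feeder list, which stood only at percentile 96.6 of 10000 random lists of the same size and expression. Without the 2 arrays farthest from the median score r was 0.975, and around the genotype means it was 0.958. The second component (19.4%) is uncorrelated with the first by construction. Its correlation with the feeder score was therefore bound to be low and adds no information (r = -0.027, exact permutation p = 0.944, rho = -0.28, exact permutation p = 0.463). Without the 2 farthest arrays r was 0.17. On that component Terc+/+ replicates 1 and 2 stood at 24.2 and 26.1, Terc+/+ replicate 3 at 0.050, the Terc+/- arrays between -14.1 and 3.97 and the Terc-/- arrays between -12.3 and -10.2. Pou5f1, which encodes the pluripotency factor Oct4, rose with the feeder score (r = 0.742, exact permutation p = 0.0166, adjusted 0.0249; rho = 0.733, exact permutation p = 0.0311, adjusted 0.0467). Its r was 0.595 without the 2 farthest arrays.

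**Figure D1:**
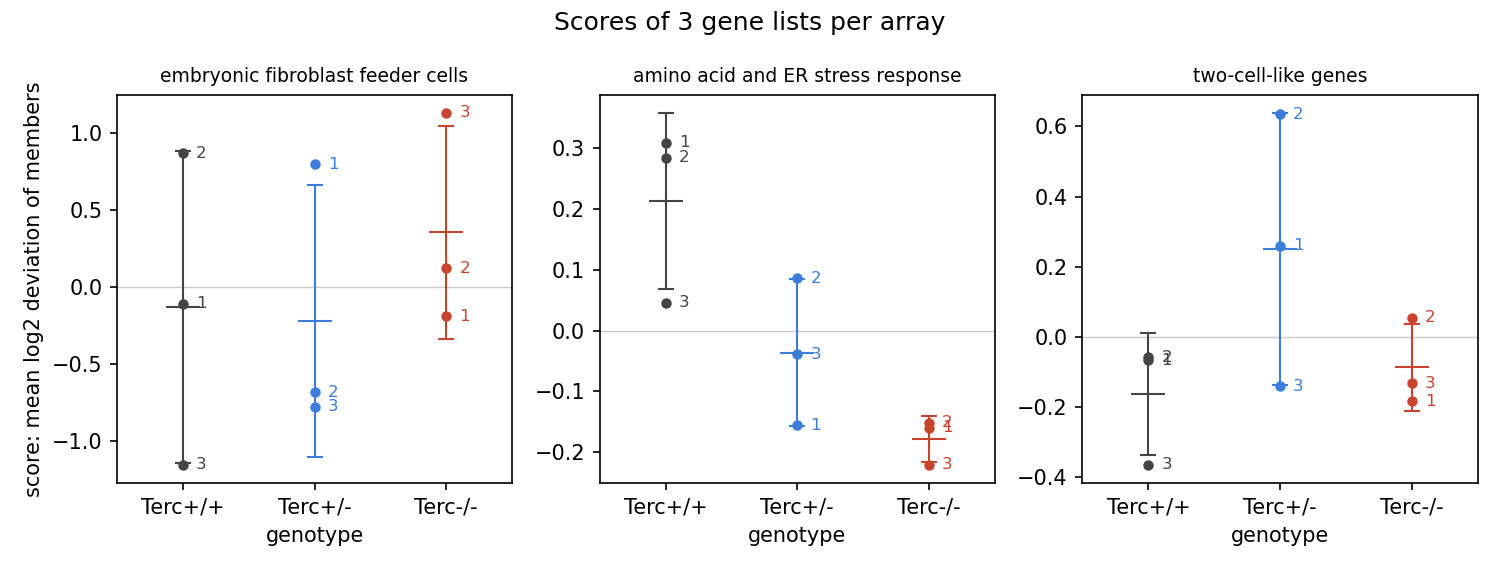
Score of 3 gene lists in each array (mean log2 deviation of the list's members from their mean over the 9 arrays, y axis) by Terc genotype (x axis); points are arrays with their replicate number, dashes and bars the mean and SD of 3 arrays. The feeder score runs from -1.16 in Terc+/+ replicate 3 to 1.13 in Terc-/- replicate 3, the amino acid and ER stress score lies below all Terc+/+ arrays in the 3 Terc-/- arrays, and the two-cell-like score is highest in Terc+/- replicate 2.

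Terc-/- ntESCs differed from Terc+/+ ntESCs in 10 features, 8 higher and 2 lower. The largest fall was in Pltp, the phospholipid transfer protein, from 9.14 ± 0.15 to 7.91 ± 0.11 (SD, n = 3), or 2.34-fold (adjusted p = 0.0458). Agpat4, an acyltransferase that makes phosphatidic acid, fell by 0.75 (SE 0.08). Srf, the serum response factor, rose from 9.06 ± 0.18 to 10.08 ± 0.18, or 2.03-fold (adjusted p = 0.0474), and Ncl, which encodes nucleolin, a nucleolar protein of ribosome production, rose from 10.00 ± 0.07 to 10.98 ± 0.19, or 1.98-fold. The RNA helicase gene Ddx3x rose 1.82-fold, Ccdc58 1.75-fold, and Lin28a, whose product binds RNA and blocks maturation of the let-7 microRNA, 1.74-fold. Gpd2, a mitochondrial glycerol-3-phosphate dehydrogenase, rose 1.64-fold, and Morc2a, an ATPase of heterochromatin silencing, 1.56-fold. The tenth feature, probe 5090204, has no gene in the annotation used and rose 1.96-fold.

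Adjusted p-values of these 10 lay between 0.0458 and 0.0474, close to the threshold. In each of the 10 all 3 Terc-/- arrays lay on 1 side of the 3 Terc+/+ arrays, which a choice by small p favours and which adds no support. Second probes of Ncl, Lin28a, Gpd2 and Pltp had the same sign (0.92, 0.71, 0.47 and -0.61), whereas a dimmer second probe of Srf gave -0.25. An unadjusted p under 0.05 was reached by 1980 features, against 933.3 by chance, and 14.9% of features did not overlap between the genotypes, against 10% by chance. The count rested on single arrays and on the model: it was 0 without any 1 of 7 arrays (Terc+/+ replicates 1 and 2, Terc+/- replicates 2 and 3, and each Terc-/- replicate), 4 without Terc+/- replicate 1, and 287 without Terc+/+ replicate 3. It was also 0 with only the arrays of both genotypes, with trend and robust variance, with a minimum fold of 1.2 and among genes with a mean above 6, and 2999 with array quality weights.

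**Figure D2:**
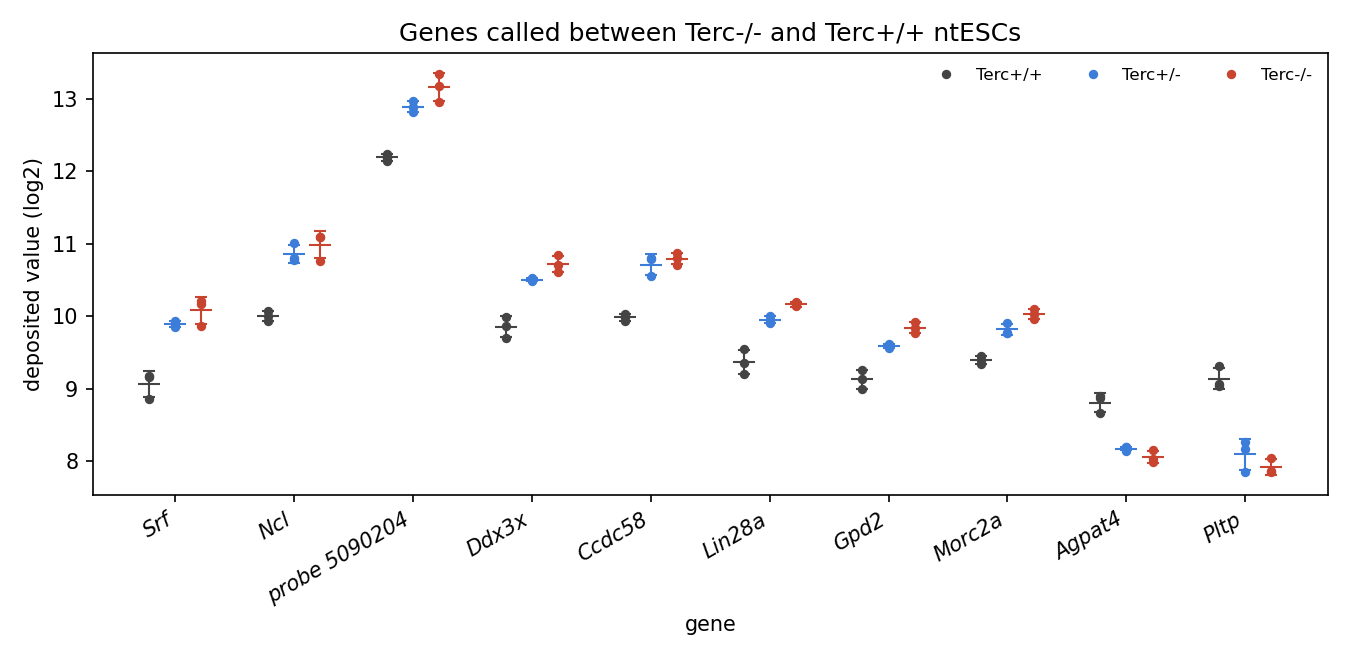
Deposited log2 values (y axis) of the 10 features called between Terc-/- and Terc+/+ (x axis), for each array of the 3 genotypes; points are arrays, dashes and bars the mean and SD of 3 arrays. The Terc+/- arrays lie on the side of the Terc-/- arrays in each feature, for Pltp at a mean of 8.09 against 9.14 in Terc+/+ and 7.91 in Terc-/-.

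Genes of the amino acid and ER stress response were lower in Terc-/- than in Terc+/+ as a list. These genes are induced by the transcription factor ATF4 or by unfolded protein in the endoplasmic reticulum. Of 31 measured members 26 had a lower mean, the median log2 fold change was -0.28, and camera gave an adjusted p of 1.98e-06 (adjusted p = 0.17 with an estimated correlation, 0.0388 with fry). None passed over all genes (0 of 31), and 2 passed adjusted over the list alone: Ddit3, which encodes CHOP (-1.05, SE 0.19), and Ddit4 (-1.42, SE 0.32). The values were -0.86 for Atf4 (SE 0.25) and -0.61 for Creld2 (SE 0.17), neither past either threshold. Leaving out any 1 of the 9 arrays kept the call, with medians from -0.41 to -0.21.

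Pluripotency genes did not pass as a list in Terc-/- against Terc+/+. Among 30 measured naive and core members the median was -0.096 (camera adjusted p = 0.84), 1 member, Lin28a, was called over all genes, and 3 were higher adjusted over the list alone: Lin28a, Sall4 (0.43, SE 0.08) and Gbx2 (1.06, SE 0.27). Tcl1 (-0.74, SE 0.23) and Klf2 (-0.73, SE 0.27) did not pass. In the glycolysis list (23 measured, median -0.10, adjusted p = 0.0799) Hk1, the first enzyme of the pathway, was lower adjusted over the list alone (-0.94, SE 0.13) and Pgk1 higher (0.54, SE 0.11). Feeder markers had a median of 0.47, with 36 of 42 higher, and did not pass (adjusted p = 0.0581, and 0.97 with an estimated correlation). Trophoblast genes (-0.14, adjusted p = 0.0581), immediate early genes (-0.21, 0.0581) and p53 targets (-0.12, 0.0799) did not pass either.

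The other lists had adjusted p-values between 0.304 and 0.972 in this comparison. Their medians were 0.047 for telomerase and telomere proteins, 0.029 for two-cell-like genes, -0.065 for primed epiblast, -6.9e-05 for neuroectoderm, 0.021 for mesoderm and primitive streak, -0.0095 for endoderm, 0.0042 for epidermis and keratinocytes, -0.078 for macrophages and blood and -0.020 for endothelium. For DNA damage signalling and repair the median was -0.041, for mitochondrial biogenesis regulators 0.021, for oxidative phosphorylation 0.00027, for hypoxia-induced genes 0.038, for the heat shock response 0.0074, for cholesterol synthesis -0.014 and for the cell cycle 0.041. DNA methylation and demethylation genes had a median of 0.029, methylation-silenced germline genes -0.028, imprinted genes -0.027, Y-linked genes with Xist 0.14, the interferon response 0.028, TGF-beta and BMP targets 0.043 and Wnt targets 0.027. Within these lists single members passed adjusted over the list alone but not over all genes. Eif1a, Robo4, Esam, Rpa1, Nrf1, Kdm3a, Notum and Cdx1 were higher, and Krt17, Vwf, Xrcc1, Cat, Ddit4 (in the hypoxia list), Hspa1a, Ccnd3 and Dio3 were lower. The median and the test pointed opposite ways in 6 uncalled lists here and in 3 and 0 in the comparisons that follow, and median and mean differed in sign in 10, 7 and 4 lists, none of them called.

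None of the genes named in advance passed the threshold between Terc-/- and Terc+/+, with standard errors that leave sizeable differences possible for some. Pou5f1 was 12.09 ± 0.32 in Terc-/- and 11.99 ± 0.80 in Terc+/+ (SD, n = 3; adjusted p = 0.965). Sox2 gave -0.45 (SE 0.35) with its brightest probe and 0.39 with another. Zscan4c, a gene of the two-cell-like state, gave 0.62 (SE 0.75). Xist, the RNA that silences an X chromosome in female cells, gave 0.46 (SE 0.33), and the 7 Y-linked genes Sry, Zfy1, Zfy2, Uty, Usp9y, Kdm5d and Eif2s3y lay between -0.067 and 0.30 with adjusted p-values from 0.731 to 0.981. Means of Sry, Zfy2 and Usp9y lay between 5.36 and 5.66 in all 3 genotypes, near the lowest value of 5.11, so their differences say little. Eif2s3y was the brightest of the 7, with means of 9.64 in Terc+/+, 9.95 in Terc+/- and 9.94 in Terc-/-.

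In Terc+/- against Terc+/+ no gene was called (0 of 18666 with limma). An unadjusted p under 0.05 was reached by 1603 features, against 933.3 by chance, the smallest adjusted p was 0.105, and 12.6% of features did not overlap, against 10% by chance. The 5 smallest p-values of higher genes were those of Ccdc58 (0.73, SE 0.09), Ncl (0.86, SE 0.11), Ddx3x (0.65, SE 0.09), Srf (0.83, SE 0.12) and Nsun2 (0.64, SE 0.09), an RNA cytosine methyltransferase. Those of lower genes were Mapkapk3 (-0.80, SE 0.09), Pltp (-1.05, SE 0.13), Gpx2, a glutathione peroxidase (-1.50, SE 0.18), Plekhf1 (-0.72, SE 0.09) and Ephx2, the soluble epoxide hydrolase (-1.09, SE 0.13). None of these 10 was past the threshold (adjusted p between 0.105 and 0.121). In each the arrays of both genotypes did not overlap, which a choice by smallest p favours. The count was 28 without Terc+/+ replicate 3 and 643 with array quality weights.

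Two-cell-like genes were higher in Terc+/- than in Terc+/+ as a list. These are transcripts of the two-cell embryo that a small share of embryonic stem cells makes at any time. Of 23 measured members 20 had a higher mean, with a median of 0.23 (camera adjusted p = 0.000135, adjusted p = 0.64 with an estimated correlation, 0.391 with fry). None passed over all genes or adjusted over the list alone (0 and 0). Tcstv3 (1.48, SE 0.51), Tcstv1 (0.89, SE 0.38) and Zscan4c (1.94, SE 0.75) were higher in mean without passing. The list's scores were 0.26, 0.64 and -0.14 in Terc+/- replicates 1, 2 and 3, and without replicate 2 the median was 0.10 (adjusted p = 0.0476).

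Targets of p53, the amino acid and ER stress response and immediate early genes were lower in Terc+/- than in Terc+/+ as lists. Targets of the tumour suppressor p53 had a median of -0.20, with 30 of 40 members lower (camera adjusted p = 0.000204, adjusted p = 0.16 with an estimated correlation, 0.0450 with fry). Abhd4 (-0.62, SE 0.13), Apaf1 (-0.53, SE 0.14) and Phlda3 (-0.89, SE 0.25) had the smallest p-values, and 0 passed over all genes or adjusted over the list alone. With the feeder score in the model, chosen after seeing the data, 15 members were lower and 1 higher adjusted over the list alone, Cdkn1a (-0.43) and Mdm2 (-0.26) among the lower, and 2 were lower over all genes. The amino acid and ER stress response had a median of -0.17, with 24 of 31 lower (camera adjusted p = 0.000466, adjusted p = 0.29 with an estimated correlation, 0.201 with fry); the value for Ddit3 was -0.81 (SE 0.19). Its median was -0.091 without Terc+/+ replicate 1, -0.27 without Terc+/+ replicate 3 and -0.27 without Terc+/- replicate 2, all still called. Immediate early genes, which share Atf3 with that list, had a median of -0.21, with 16 of 18 lower (camera adjusted p = 0.0103, adjusted p = 0.64 with an estimated correlation, 0.478 with fry). That call was lost without Terc+/- replicate 3 (-0.11, adjusted p = 0.239) or Terc+/+ replicate 1 (-0.20, adjusted p = 0.0686), and the median was -0.36 without Terc+/- replicate 1.

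The other 26 lists did not pass in Terc+/- against Terc+/+ (adjusted p between 0.0556 for endoderm and 0.979), feeder markers among them (median -0.081, adjusted p = 0.748), although those passed as lower without Terc+/+ replicate 3 (-0.64) or Terc+/- replicate 1 (-0.65). Wnt targets had a median of 0.096 (camera adjusted p = 0.0716) and passed with fry (0.0280), with Lef1 higher adjusted over the list alone (0.94, SE 0.19). The same 3 pluripotency genes, Lin28a, Sall4 and Gbx2, were higher adjusted over their list alone, and Hk1 was lower (-0.86, SE 0.13). Pou5f1 (0.054, SE 0.37), Sox2 (-0.24, SE 0.35) and Xist (-0.12, SE 0.33) did not pass, and the Y-linked genes lay between 0.036 and 0.31 with adjusted p-values from 0.605 to 0.945.

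Between Terc-/- and Terc+/- no gene was called (0 of 18666 with limma). Only 328 features had an unadjusted p under 0.05, fewer than the 933.3 that chance gives, and 7.70% of features did not overlap, against 10% by chance. The 5 smallest p-values of higher genes were those of Washc5 (0.41, SE 0.08), Taf15 (1.09, SE 0.23), Dus4l (0.57, SE 0.13), Kirrel2 (0.40, SE 0.09) and Fam169b (0.28, SE 0.07), and those of lower genes Prcc (-0.38, SE 0.07), Gpr141b (-0.31, SE 0.07), Rpl22 (-0.37, SE 0.09), G6pc3 (-0.35, SE 0.09) and Cuedc2 (-0.26, SE 0.07). All 10 had an adjusted p of 1.00. Zscan4c gave -1.32 (SE 0.75), Xist 0.58 (SE 0.33), Pou5f1 0.040 (SE 0.37), Sox2 -0.21 (SE 0.35) and the Y-linked genes -0.12 to -0.011, none past the threshold.

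Glycolysis genes were lower in Terc-/- than in Terc+/- as a list, with 20 of 23 members lower and a median of -0.25 (camera adjusted p = 3.79e-06, adjusted p = 0.50 with an estimated correlation). Values were -0.46 for Aldoa (SE 0.18), -0.39 for Pgam1 (SE 0.15) and -0.35 for Eno3 (SE 0.10), with 0 members past the threshold over all genes or over the list alone. With the feeder score in the fit the median was -0.17, still called (9.11e-05, and 0.70 with an estimated correlation). Two-cell-like genes were lower (-0.17, 19 of 23 lower, adjusted p = 2.74e-06, adjusted p = 0.74 with an estimated correlation), with -0.097 without Terc+/- replicate 2 and -0.28 without Terc+/- replicate 3.

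Feeder markers were higher in Terc-/- than in Terc+/-, with 40 of 42 higher and a median of 0.53 (camera adjusted p = 2.74e-06, adjusted p = 0.82 with an estimated correlation). The call was lost without Terc-/- replicate 3 (0.14, adjusted p = 0.402) or Terc+/- replicate 3 (0.31, 0.0648), and the median moved to 1.12 without Terc+/- replicate 1, 0.89 without Terc-/- replicate 1 and 0.33 without Terc+/- replicate 2. The amino acid, DNA damage and p53 lists passed at an adjusted p of 0.0255. The amino acid and ER stress response was lower (-0.13, adjusted p = 0.68 with an estimated correlation), a call lost without Terc+/- replicate 2 (-0.0022, adjusted p = 0.200) or Terc-/- replicate 1 (-0.11, 0.0805). DNA damage signalling and repair genes were lower (-0.071, adjusted p = 0.79 with an estimated correlation), a call lost without Terc-/- replicate 3 (-0.0029, 0.779), Terc+/- replicate 2 (-0.076, 0.319) or Terc+/- replicate 3 (-0.064, 0.0608), with medians of -0.12 without replicate 1 of either genotype. It was also lost with cyclic loess (-0.048, adjusted p = 0.0737), trend and robust variance (0.0704) and array quality weights (0.0848). Targets of p53 were higher (0.088, adjusted p = 0.50 with an estimated correlation), a call lost without Terc-/- replicates 2 (0.096, 0.0747) or 3 (0.053, 0.260) or Terc+/- replicates 2 (0.066, 0.144) or 3 (0.12, 0.0608), with 0.14 without Terc-/- replicate 1, and lost with trend and robust variance (0.0567). With the feeder score in the fit, the amino acid (-0.18, adjusted p = 0.0596), DNA damage (-0.061, 0.387) and p53 lists (0.11) no longer passed. Their medians stayed near or above those without the score in size. The mean of the DNA damage list shrank from -0.074 to -0.045, with 35 and then 28 of 48 members lower. The mean of p53 targets went from 0.115 to 0.086, and that of the amino acid list from -0.141 to -0.144. Whether feeder content made part of these shifts stays open. The feeder list itself cannot pass in that model, since the score is the mean of its markers. With fry 0 lists passed in this comparison. The other 24 lists did not pass with camera (adjusted p between 0.0595 for hypoxia-induced genes and 0.828).

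**Figure D3:**
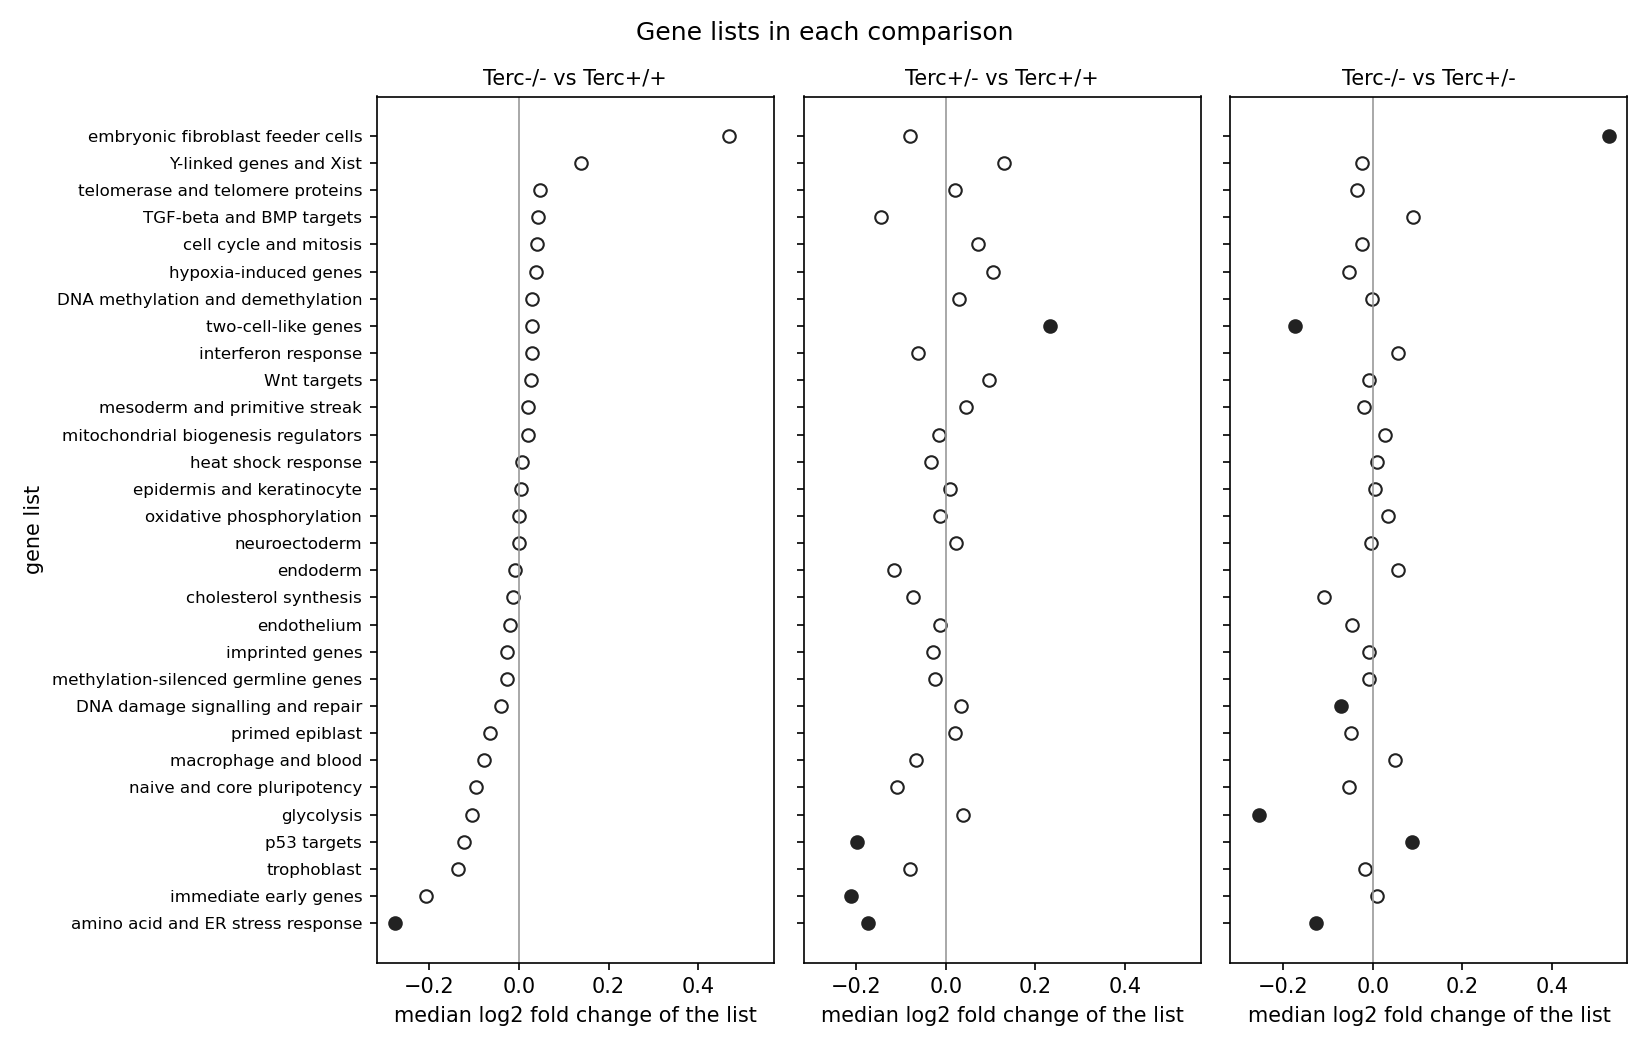
Median log2 fold change (x axis) of each of the 30 gene lists (y axis) in the 3 comparisons; filled points passed camera at an adjusted p under 0.05 with the preset correlation of 0.01, open points did not. The amino acid and ER stress response is filled in all 3 panels (-0.28, -0.17 and -0.13), and no list passed with an estimated correlation.

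Both mutant genotypes lay on the same side of Terc+/+ for the 10 called features, with Terc+/- between Terc+/+ and Terc-/- in mean. Choosing features for their difference between Terc-/- and Terc+/+, with the same Terc+/+ arrays in both comparisons, favours this pattern, so it is no evidence of a shared change or of a dose effect. The fold changes of the 2 comparisons correlated across genes (r = 0.803; genes are not independent replicates), but they share the Terc+/+ arrays. In 1000 simulations of unchanged groups against shared controls r averaged 0.467, with 95% between -0.46 and 0.941. The covariance was 0.0464 against a simulated mean of 0.0215 (95% between -0.013 and 0.0820), a difference of 0.0250. The observed value therefore lay within what shared control arrays alone gave. The 3 controls cannot be split into parts of at least 2 arrays, so part of the excess may come from them.

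With the feeder score added to the model, a choice made after seeing the data, 133 features were called in Terc-/- against Terc+/+ (60 higher, 73 lower), 178 in Terc+/- against Terc+/+ (70 higher, 108 lower) and 0 between Terc-/- and Terc+/- (602 at an unadjusted p under 0.05). All 10 earlier calls were among the 133. The 2 sets shared 82 features, 28 higher and 54 lower, with 0 in opposite directions, against 0.225 and 0.422 for independent lists. Because both sets use the same Terc+/+ arrays, independent lists are not the value expected without a change, and shared controls alone favour the same sign. These counts were not stable: leaving out 1 array gave 0 to 1658 in the first comparison and 0 to 848 in the second. In the first comparison the count was 0 without Terc+/+ replicate 1 or 2, Terc+/- replicate 3 or any 1 Terc-/- replicate, 258 without Terc+/- replicate 1 and 1658 without Terc+/+ replicate 3. In the second it was 0 without Terc+/+ replicate 2, Terc+/- replicate 1 or 3 or Terc-/- replicate 2, 1 without Terc+/- replicate 2, 14, 18 and 41 without Terc-/- replicate 3, Terc+/+ replicate 1 and Terc-/- replicate 1, and 848 without Terc+/+ replicate 3.

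The largest fall of both mutants in that model was that of the tight junction gene Cldn4, by 3.08-fold in Terc-/- (adjusted p = 0.0442) and 3.79-fold in Terc+/- (adjusted p = 0.0252). Also lower in both were the membrane protease gene St14 by 2.31-fold and 2.35-fold, Apoe by 2.13-fold and 2.66-fold, Gpx2 by 2.35-fold and 2.84-fold, Csf2ra by 2.08-fold and 2.10-fold and Pltp by 2.25-fold and 2.08-fold. In Terc-/- the largest falls also took in Cmtm7 (2.25-fold), Ddit3 (2.20-fold), the glutathione transferase gene Gstm1 (2.07-fold) and the cytokine gene Osm (2.06-fold), and in Terc+/- Stx3 (2.33-fold), Rgcc (2.24-fold), Ephx2 (2.14-fold) and Car13 (2.00-fold). Higher in both were the homeobox gene En2 (2.14-fold and 2.05-fold), the splicing core gene Snrpd1 (1.95-fold and 2.26-fold) and Ndufa5 of respiratory complex I (1.84-fold and 2.32-fold).

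In Terc-/- the largest rises in that model also included Taf13 (2.11-fold), Srf (2.04-fold), Ncl (2.00-fold), Zbtb8os (1.99-fold), Pcyt1a (1.97-fold), Pes1, a factor of ribosome assembly (1.89-fold), and Smim26 (1.82-fold). In Terc+/- they included Robo4 (3.20-fold), the ribosomal protein genes Rpl30 (2.44-fold) and Rpl36al (2.07-fold), Ubl5 (2.13-fold), the proteasome gene Psma4 (2.07-fold), Nup37 (2.04-fold) and Cir1 (2.03-fold). Other probes of Robo4 (0.097 and 0.016), Nup37 (-0.32) and Cir1 (-0.086) did not follow in Terc+/- in the fit without the score, so these values are uncertain. The means of these probes were 5.57 and 5.72 for Robo4 and 5.72 for Nup37, below the median value of 5.94, where a change may not show. For Cir1 the mean was 7.06. Adjusted p-values of these largest rises and falls lay between 0.0218 and 0.0483.

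Called members of lists in that model were few. Lin28a, Ndufa5 and Tex11, a germline gene, were higher in both mutants, and Hk1, Krt17, Egfl7, Dio3, Apoe and the p53 target Abhd4 were lower in both. In Terc-/- Cat, which encodes catalase, and the imprinted gene Slc22a18 were also lower. In Terc+/- Nop10, a protein of the telomerase complex (2.04-fold, adjusted p = 0.0499), Lef1, Nsdhl, Atp5j and Uqcrh were also higher and Apaf1 was lower. In Terc-/- Nop10 gave a 1.96-fold higher value with an adjusted p of 0.0673. In the fit without the score, other probes of Nop10 (0.050), Lef1 (-0.21) and Atp5j (0.12 and -0.40) in Terc+/- and of Gstm1 (-0.11) and Slc22a18 (-0.062) in Terc-/- did not follow either, and 1 of 2 other probes of Egfl7 and of Stx3 did not. Among these probes, those of Lef1 (mean 5.55), Gstm1 (5.91), Slc22a18 (5.79) and Stx3 (5.72) lay below the median value of 5.94, where a change may not show. The amino acid and ER stress response (-0.28, adjusted p = 1.34e-06), p53 targets (-0.13, 0.00336) and immediate early genes (-0.26, 0.00336) passed camera in Terc-/- against Terc+/+ with the score, with adjusted p-values of 0.26, 0.72 and 0.72 with an estimated correlation. In Terc+/- against Terc+/+ two-cell-like genes (0.23, adjusted p = 0.000695) and Wnt targets (0.12, 0.0385) passed as higher, and p53 targets (-0.20, 1.12e-05), the amino acid and ER stress response (-0.16, 0.000779), immediate early genes (-0.21, 0.0102), endoderm (-0.082, 0.0310) and trophoblast genes (-0.081, 0.0385) as lower, all with an adjusted p of at least 0.37 with an estimated correlation.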

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

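All alternatives named as added were chosen after seeing the data: cyclic loess, background subtraction, filters on the mean, and the feeder score. The 10 calls in Terc-/- against Terc+/+ became 31 with cyclic loess, 133 with the feeder score, 2999 with array quality weights and 5 with probes averaged. They became 0 with background subtraction, among genes above the median in mean, with means above 6, 6.5, 7 or 8, with only the arrays of both genotypes, with trend and robust variance and with a minimum fold of 1.2. The 0 calls in Terc+/- against Terc+/+ became 643 with weights and 178 with the score. Calls in both mutants went from 0 to 589 and 82. Terc-/- against Terc+/- stayed at 0 under all of them. The weights ran from 7.01 for Terc+/+ replicate 1 to 0.214 for Terc+/+ replicate 3. The causes were not tested.

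Leaving out 1 array gave 0 to 287, 0 to 28 and 0 to 0 calls in the 3 comparisons in the order above, 0 to 28 in both mutants, and 1 to 7, 3 to 8 and 4 to 8 lists. With the score it gave 0 to 1658, 0 to 848 and 0 to 0. Fits with fewer arrays have less power, but 287 and 1658 came without Terc+/+ replicate 3.

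Lists called in Terc-/- against Terc+/+ went from 1 to 4 with background subtraction, trend and robust variance or averaged probes, 2 above the median in mean or with weights, and 3 with the score. In Terc+/- against Terc+/+ they went from 4 to 7 above the median in mean or with the score and 2 with fry, and in Terc-/- against Terc+/- from 6 to 9 above the median in mean, 7 with background subtraction or averaged probes, 4 with trend and robust variance, 2 with the score, 0 with fry and 5 with cyclic loess, which ended the call of DNA damage signalling and repair (-0.048, adjusted p = 0.0737). With an estimated correlation they were 0 in all 3 comparisons. Immediate early genes in Terc-/- against Terc+/- did not pass in the main fit (median 0.010, camera adjusted p = 0.771). Without Terc-/- replicate 3 they passed as lower (-0.198, camera adjusted p = 0.0311), where leaving out Terc-/- replicate 1 gave 0.113. Apart from that case, 41 list results lost and 70 gained a call, where each list, comparison and alternative setting counts as a separate result. Of the results of named genes, counted the same way, 166 lost and 22 gained a call and 0 reversed. The same gene or list can thus be counted many times. Directions were compared where a value passed in the main fit, in the alternative or in both.

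With the score in the model, the 133 calls became 79 with cyclic loess, 46 with background subtraction and 2062 with weights, and the 178 became 99 with background subtraction and 947 with weights.

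With the replicate number as a block, calls in Terc-/- against Terc+/+ went from 10 to 0, and with the score from 133 to 0 and from 178 to 0. No pairing by number was seen: deviations of same-numbered arrays correlated between -0.60 and 0.45, and 3 of 9 arrays matched their own number best. The feeder axis was not removed from these deviations and could hide a pairing, so none is excluded.

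Not run, for want of raw signals tied to samples, were log2 signals without normexp, an offset of 50, median scaling and detection filters. Without detection p-values the signal over background stays unknown: the median gene's mean was 6.00, against a lowest value of 5.11.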

Other observations

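Tests of the feeder axis, of a feeder difference between genotypes and of both two-cell-like explanations were chosen after the results were seen, as was the model with the feeder score; the others were set before.

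Zscan4c varied widely within Terc+/-. Its deposited log2 values were 8.99, 9.71 and 6.95 in Terc+/- replicates 1, 2 and 3, 7.28, 6.98 and 5.56 in the Terc+/+ replicates and 6.57, 7.89 and 7.22 in the Terc-/- replicates. The two-cell-like genes moved together around the genotype means, with a mean pairwise correlation of 0.445, at percentile 100 of 10000 random lists of the same size and expression. A candidate explanation is a share of two-cell-like cells that differs between cultures. A difference of genotype alone gives no joint variation around the genotype means, so it does not account for all of their variation. The correlation was also at percentile 100 of 1000 random lists in each of the 9 sets without 1 array (0.32 to 0.48), but these sets share most arrays. Random lists were not matched on shared regulation, so the percentile does not tell what made these genes vary together. A genotype effect on top of this variation stays open.

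The main axis of variation followed the feeder markers (r = 0.937), but random lists of the same size and expression followed it less closely in only 96.6% of draws, short of the bound set for the test, so a differing share of feeder fibroblasts stays a hypothesis. The protocol removed the fibroblasts before extraction. Of the 42 markers, 32 lay above the array's median even in the array with the lowest score, and 1 is in another list. Pou5f1 was lowest in that same array (11.13, against 11.72 to 12.70 in the others), which dilution of stem cells by fibroblasts does not give. Other stem-cell markers went another way. The primed epiblast score was highest in that array (0.425), and Sox2 was lowest in Terc-/- replicate 3 (8.83), which had the highest feeder score. The naive and core pluripotency score was -0.07 in that array and lowest in Terc+/- replicate 1 (-0.197). These markers therefore do not decide on dilution, and mesenchymal differentiation in the cultures was not tested apart. For Terc+/+ replicate 3, a linear effect of the feeder score alone is argued against. With the score in the model its residual variance was still 3.09 times the median of the other arrays, whose highest was 1.51 times. A mixture of cells need not act linearly on log2 values, so this does not decide on a low share of fibroblasts alone.

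Terc+/+ may stand apart from both mutant genotypes, which did not differ from each other in any called gene. For 1186 of 18666 features the Terc+/+ arrays did not overlap the 6 mutant arrays, where chance gives 2.38% of features. These features kept a median of 0.984 of their log2 difference once the score was in the model (5th percentile 0.912). The score itself overlapped, from -1.16 to 0.87 in Terc+/+ and from -0.78 to 1.13 in the mutants, so features that follow it were left out. The kept share therefore cannot decide whether a feeder difference between genotypes was the cause. Whether chance alone grouped the arrays was tested over all 84 splits into 3 and 6: with the score the real split called 582 features and 1 other split more (637, Terc+/+ replicates 1 and 2 with Terc+/- replicate 2), so 2 of 84 were as large, which argues against a random grouping of the arrays in that model, chosen after the fact, and says nothing of what set the Terc+/+ arrays apart. Chance values of the shared Terc+/+ arrays stay open, since the covariance of 0.0435 with the score lay within the error of the upper simulated bound (0.0408, between 0.0373 and 0.0442; this allowance for error was added after the value was seen), and so does the array on another chip, because which sample it was is not given: the genotypes separated fewer genes than another split with all 9 arrays (1943 against 2126, with the score regressed out) and in 5 of 9 sets without 1 array (ratios from 0.713 without Terc+/+ replicate 2 to 2.29 without Terc+/+ replicate 3), so leaving out arrays did not test it. Lines derived or cultured apart were not tested, and the Terc genotype itself stays among the open explanations.

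Without the score, the real split of 3 Terc+/+ arrays against 6 called 113 features, and another split, of Terc+/+ replicate 2, Terc+/- replicate 1 and Terc-/- replicate 3, called 335. Those are the 3 arrays with the highest feeder scores (0.87, 0.80 and 1.13), which points to that structure of the samples.

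Splits of 6 arrays into 3 and 3 number 10, too few for a share under 0.05. The arrays of the third genotype stayed in each fit under their own label. With only the arrays of both genotypes, Terc-/- against Terc+/+ gave 0 calls in the real split. The real split called 10 features in Terc-/- against Terc+/+, with 0 in the highest other (1 of 10 splits as large). In both other comparisons the real split and the highest other called 0 (10 of 10 splits as large). With the score, the real splits called 133 and 178 against Terc+/+, with 0 in the highest other (1 of 10 each), and 0 between Terc-/- and Terc+/-, with 0 in the highest other (10 of 10).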
